A study of Mus musculus with 2 samples.

How the data were processed

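Single-cell RNA sequencing libraries of mouse liver, 1 from WT and 1 from DKO mice (labelled with an Alb-CreERT2 transgene and loxP-flanked Pten and Traf3), were analysed from tables of counts. The count tables deposited by the authors hold UMI counts per cell barcode and gene, made with the BD WTA Rhapsody Analysis Pipeline version 1.8 on GRCm38 with GENCODE M19, per the file headers. UMI errors were corrected by the recursive substitution method of that pipeline, per the file names, and the counts were not normalised; the submitters' processing notes name mm10, the same build. Per the labels' protocols, mRNA was taken from fresh tissue with the BD Rhapsody cartridge reagents and the libraries were converted for DNBSEQ sequencing. How the liver was dissociated, how cells were selected and when recombination was induced is not given in the sources used here. All values of both tables were checked to be whole numbers of at least 0. For WT 17469 genes and for DKO 19460 genes were listed, with 16183 in both, 1286 in WT alone and 3277 in DKO alone; a gene not listed for a library was taken as 0 there. A sheet of bead label sequences given with the series holds no measurement and was not used.

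Barcodes with 200 detected genes or more and at most 50% mitochondrial UMIs were kept. In WT 10323 barcodes fell under 200 genes and 11569 over 50%, and in DKO 857 and 1556. Doublets were called per library with Scrublet as run by scanpy 1.11.5, at automatic thresholds of 0.361 in WT and 0.524 in DKO. It called 2 of 10895 cells (0.0184%), a rate so low that the caller has not worked, so the kept cells are in effect not cleaned of doublets. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen over both libraries, and 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, seed 1) gave 26 clusters, without integration of the libraries. The filters, the cluster settings, the gene lists, the cell type markers, the rule for named genes and most alternatives were chosen before the data were examined. The thresholds of the naming rule were chosen after the data were seen. For each cluster the class other than hepatocytes with the highest mean log2 fold of its markers over the other clusters, with 25 CPM added, was taken first. Its name was given if that mean was 1.5 or more, with 3 or more markers up and seen in 5% of cells or more. The 10 leading genes also had to hold no more markers of another class than of that class. Clusters left over could be named hepatocyte-like by a weaker rule. It asked for a mean fold of hepatocyte markers of 0.3 or more over the clusters already named, and 3 or more such markers with 10 UMIs or more. Fewer than 3 markers of any other class could be up. No hepatocyte marker had to be up over all other cells, and clusters 0, 3, 5, 9 and 11 had 0 up. Names are therefore written as X-like. Libraries were compared over a class as a whole and not cluster against cluster, but genes that lead clusters made up mostly of 1 library are among the named genes.

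UMIs were summed over all kept cells and over the cells of each class with 50 cells or more in both libraries (hepatocyte-like, B cell-like and T cell-like). The log2 ratio, DKO over WT, was taken of counts per total (CPM) after adding 0.5 UMIs, with an exact conditional 95% interval of the ratio and exact Poisson intervals of levels; shares of cells carry exact Clopper-Pearson intervals. With 1 library per group no test between genotypes, p-value or count of changed genes was made, since cells are not replicates. A gene was measured with 20 UMIs or more over both libraries, and a list with 5 such members or more. The median log2 ratio of each of 34 lists was set against 10000 random lists of the same size drawn in 20 bins of mean expression, and called high or low at or beyond the 97.5 and 2.5 percentiles. A member counted as higher or lower with a ratio of 2-fold or more whose interval excluded 1. Relative values have the median of all measured genes taken off. A fold against 0 UMIs is given against a floor of 3 UMIs (an exact two-sided 95% interval for 0 reaches 3.69 UMIs, so its lower limit of the fold is smaller), summed over the library, which is 0.844 CPM over all kept WT cells and 1.11 CPM in hepatocyte-like WT cells. Named genes were Pten and Traf3, up to 10 genes with the highest and 10 with the lowest log2 ratio among genes with 100 UMIs or more, up to 4 members with the largest log2 ratio of each called list, and any list member given with its values. For the highest and lowest genes, that rule left out mitochondrial, predicted and Y-linked genes, Xist and immune receptor segments. Within a class it also left out genes whose level there was below that of the other cells of the library. List members were not held to this. Gene positions were taken from GENCODE M21 on GRCm38.

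The steps were tested on simulated counts with the real means and library sizes, 200 genes of which were altered by known folds. Counts were drawn as independent Poisson counts, the model behind the intervals, so their coverage checks only the computation. Differences between cells, libraries or mice, free RNA and genes that vary together were not simulated. Intervals covered the true ratio for 95.9% of 12888 genes over all cells, 96.0% of 11057 in hepatocyte-like, 96.5% of 2334 in B cell-like and 96.6% of 2993 in T cell-like cells. A 4-fold higher level was recovered for 100% of altered genes over all cells and for 98%, 84% and 96% in the 3 classes, and a 4-fold lower level for 86%, 86%, 60% and 62%. Of 100 random lists, 5, 3, 1 and 0 were called in those comparisons.

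Alternatives fixed beforehand were a limit of 25% or no limit on mitochondrial UMIs, 500 genes or more per cell, doublets kept, resolutions 0.5 and 2, each library clustered alone, other minimum counts (none and 20, or 50 and 300) and a mean over cells. Cells thinned to equal depth (400 UMIs in hepatocyte-like, 600 in B cell-like and 700 in T cell-like cells, with 117, 2 and 3 WT cells and 0 DKO cells left out), shares without hepatocyte-like and erythroid-like cells, and 3 scalings were also fixed beforehand. The scalings were edgeR 4.0.16 TMM factors, DESeq2 1.42.0 size factors and the total without mitochondrial and haemoglobin genes. A scaling moves all genes of a comparison alike, so relative medians and calls stay as they are under it, and it was counted only for Pten and Traf3; the list medians with the shift left in had the sign of the relative median for each called list under the 3 scalings. Added after the data were seen were a limit of 10% mitochondrial UMIs, cluster 4 placed in the hepatocyte-like and cluster 17 in the endothelial-like class, the removal of cluster 19, and random lists matched on GC content as well. GC content was computed from GENCODE M21 transcripts of GRCm38. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3, were used.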

Results

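Single-cell RNA sequencing of mouse liver was compared between a wild-type library (WT) and a library from mice with loxP-flanked Pten and Traf3 and a Cre recombinase, inducible by tamoxifen, under the albumin promoter (DKO). Each genotype had 1 library, so no difference below has a replicate check. The number and sex of the mice behind each library are not given in the sources used here. Both libraries were made from the C57BL/6 strain with the BD Rhapsody whole-transcriptome assay, in which each mRNA molecule is tagged near its 3' end with a unique molecular identifier (UMI). The WT library held 14393 barcodes and 61096673 UMIs, and the DKO library 10083 barcodes and 31675621 UMIs. Mitochondrial UMIs made up a median of 98.4% of the UMIs of a WT barcode and 2.81% of those of a DKO barcode. Barcodes with 200 detected genes or more and at most 50% mitochondrial UMIs were kept as cells, which left 2427 WT cells (16.9% of barcodes) with 3552587 UMIs and 8466 DKO cells (84.0%) with 23751093 UMIs. The kept cells had medians of 911 UMIs, 451 genes and 31.6% mitochondrial UMIs in WT, and 1712 UMIs, 954 genes and 1.95% in DKO. Levels are UMIs summed over the cells compared and scaled to a common total (CPM), and all intervals are exact 95% intervals that cover counting error only.

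**Figure D1:**
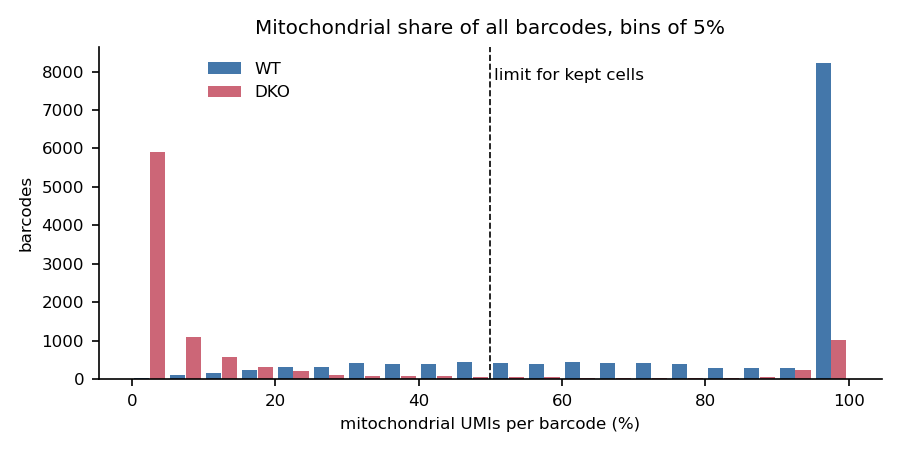
Number of barcodes by the share of mitochondrial UMIs (percent, bins of 5%) in the WT (blue) and DKO (red) libraries, before cells were chosen; the dashed line is the limit of 50% for kept cells. The median barcode held 98.4% mitochondrial UMIs in WT and 2.81% in DKO.

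The targeted genes were Pten (GRCm38, chromosome 19, 32757497 to 32826160) and Traf3 (chromosome 12, 111166370 to 111267153). In cells with a hepatocyte-like profile, Pten stood at 516 CPM (489 to 544, 1390 UMIs) in WT and 294 CPM (286 to 302, 5350 UMIs) in DKO, a ratio of 0.570 (0.537 to 0.605). The log2 ratio of Pten was -0.81 there, lay between -0.18 and -1.31 under the alternatives tried, and was negative in each of them. Traf3 in the same cells stood at 15.6 CPM (11.2 to 21.1, 42 UMIs) in WT and 16.1 CPM (14.3 to 18.1, 293 UMIs) in DKO, a ratio of 1.03 (0.745 to 1.46). The log2 ratio of Traf3 turned from 0.032 to -0.63 when cells were thinned to equal depth, with 117 WT and 0 DKO cells left out, and to -0.47 when every cell was weighted alike. It was -0.40, -0.41 and -0.32 under 3 other scalings, -0.30 without cluster 19 and 0.41 with no limit on mitochondrial UMIs, so no direction is given for Traf3. Over all kept cells Pten stood at 453 and 296 CPM and Traf3 at 18.3 and 18.5 CPM in WT and DKO. Among classes in which the albumin promoter is silent, the Pten ratio was 2.03 (1.03 to 4.57) in B cell-like, 0.805 (0.459 to 1.48) in T cell-like and 0.871 (0.585 to 1.32) in Kupffer cell-like cells. It was 0.663 (0.353 to 1.405) in the monocyte or infiltrating macrophage class (10 WT UMIs), 0.988 (0.513 to 1.98) in neutrophil-like, 1.20 (0.635 to 2.12) in endothelial-like and 1.3997 (0.773 to 2.75) in conventional dendritic cell-like cells. A 3' tag outside the deleted exons checks nothing, and the labels do not name those exons, so a transcript that lost them but kept its 3' end is counted as Pten or Traf3.

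The question of how the cell types of the liver were represented in each genotype was addressed by clustering both libraries together. Of 26 clusters, 22 were named from marker genes, 12 of them hepatocyte-like by the weaker rule for that class. All thresholds were set after the data were seen, and clusters 4, 13, 17 and 23 stayed unnamed under them. The unnamed clusters held 41 WT cells (1.69%) and 1095 DKO cells (12.9%), of which cluster 4, led by Ccl20, H19 and Rgs5, held 696 DKO cells. Hepatocyte-like cells made up 78.2% of kept WT cells and 77.0% of kept DKO cells. Endothelial-like cells made up 9.85% in WT (239 cells, 8.69 to 11.1%) and 0.224% in DKO (19 cells, 0.135 to 0.350%), a share 43.9-fold lower in DKO. The share ratio of 0.0228 was 0.050 when 500 genes were required, 0.0860 when each library was clustered alone and 0.147 with unnamed cluster 17, whose markers were endothelial, placed in the class. Endothelial marker UMIs over all kept cells, which do not depend on clusters, were also lower in DKO, at 2343 and 151.9 CPM, a ratio of 0.0648 (0.0623 to 0.0674). Cells of the class monocyte or infiltrating macrophage were 4.54 times as frequent in DKO (0.536% and 2.43%), and their marker UMIs stood at 521.6 CPM in WT and 1982 CPM in DKO. That share ratio was 2.12 when 500 genes were required and 0.786 when each library was clustered alone. Kupffer cell-like cells made up 1.61% in WT and 0.744% in DKO, but their marker UMIs were higher in DKO (ratio 1.36), and the share ratio was between 1.67 and 1.72 under 4 alternatives and 0.225 when 500 genes were required. That share leaves out unnamed clusters 13 (10 WT and 229 DKO cells) and 23 (2 and 54 cells). They had 8 and 9 Kupffer cell markers up, beside markers of other classes. Neutrophil-like cells made up 1.36% and 0.343%, with a ratio of 1.25 instead of 0.252 when 500 genes were required. T cell-like cells made up 2.55% and 1.83% (a ratio of 1.04 at a limit of 25% mitochondrial UMIs), and conventional dendritic cell-like cells 1.44% and 0.980% (a ratio of 0.320 instead of 0.680 when 500 genes were required). B cell-like cells made up 2.18% and 1.996%, but the ratio of 0.914 turned to 3.83 at a limit of 25%, with 4 WT cells left, and to 2.57 when 500 genes were required, with 8 left. Plasmacytoid dendritic cell-like cells made up 0.288% and 0.579%, and the ratio of 2.01 turned to 0.878 when 500 genes were required and to 0.916 at a limit of 25%. Mesenchymal-like cells made up 0.247% and 0.213%, with a ratio of 0.860 that turned to 1.54 with no limit on mitochondrial UMIs, and erythroid-like cells 0.0412% (1 cell) and 0.673%. Leaving hepatocyte-like and erythroid-like cells out of the total, endothelial-like cells made up 45.3% of WT and 1.01% of DKO cells, and the monocyte or infiltrating macrophage class 2.46% and 10.9%.

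**Figure D2:**
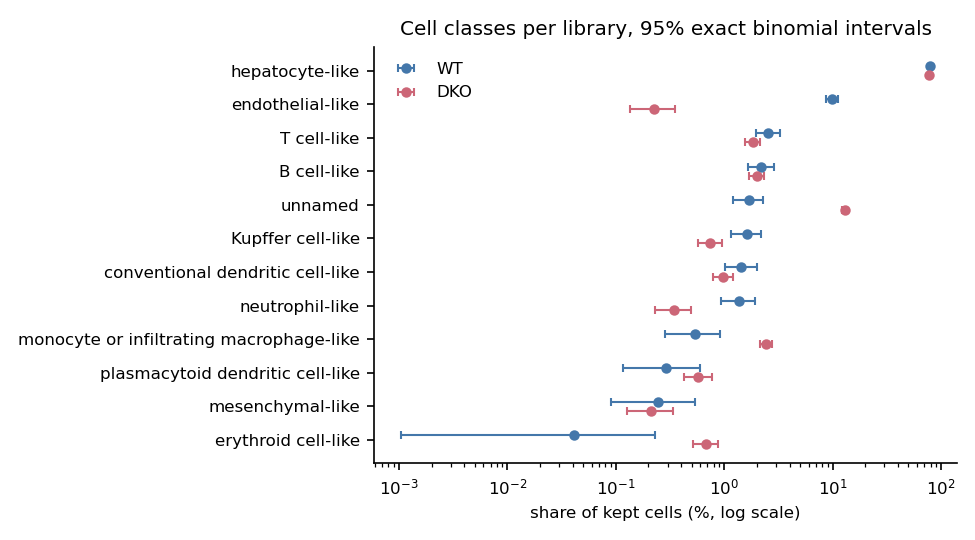
Share of kept cells (percent, logarithmic axis) in each named class in the WT (blue) and DKO (red) libraries, with exact 95% binomial intervals. The endothelial-like share was 9.85% in WT and 0.224% in DKO, and the hepatocyte-like share 78.2% and 77.0%.

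The main comparison asked how the transcripts of hepatocyte-like cells, to which the knockout was directed, differed between the libraries (1898 WT and 6523 DKO cells). In DKO, genes of cell division, of fetal liver and liver tumours, of the NF-kB pathway and of the interferon response were higher. Genes of lipid synthesis and storage and of the oxidative stress response were also higher in DKO. Genes of secreted liver proteins, drug metabolism, bile acid handling and periportal hepatocytes were lower, but 7 of the 8 low lists lost their call or turned without cluster 19 (99 WT and 14 DKO cells). The WT cells of the class lay in clusters 1 (61.0%), 6 (32.2%) and 19 (5.22%), and the DKO cells in clusters 0, 2, 3, 5, 7, 8, 9, 10 and 11, so that genotype and cluster nearly coincided. Rrm2, Birc5, Ccna2 and Cdk1 led cluster 9, with 8.32% of the DKO cells of the class, and Sprr1a, Ifit1 and Ifit3 led cluster 11, with 5.50%. No alternative was made to leave out cluster 9 or 11, so how far the high lists rest on them was not tested. Mitochondrial UMIs made up 24.6% of the UMIs of the class in WT and 3.64% in DKO, and the median log2 ratio of all genes was 0.53. Log2 ratios below are given relative to that shift unless levels are given, and counts of members are given both ways. Of 30 gene lists fixed beforehand, 11 had a median above and 8 a median below the central 95% of 10000 random lists of like expression, as a description of these libraries.

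Cell cycle genes had a median of 4.28 (3.43 with the 7 members without a WT UMI at their bound), and 23 of 24 measured members were higher and 0 lower (22 and 0 relative to the shift). Ccna2 had 0 UMIs in WT and 770 in DKO (42.3 CPM, 39.4 to 45.4), at least 37.99-fold higher against a floor of 3 UMIs, and with an exact interval of the ratio from 30.8 upwards. Ccnb1, Ccnb2 and Mki67 also had 0 WT UMIs and were at least 19.05-fold, 16.7-fold and 14.6-fold higher, as were Ckap2 and Cdc20, at least 28.6-fold and 26.1-fold. Fetal liver and liver tumour genes had a median of 3.95 (1.77 with 7 members at their bound), and 9 of 11 measured members were higher and 0 lower (8 and 0 relative to the shift). H19 (chromosome 7, 142575529 to 142578143) had no WT UMI and stood at 262 CPM in DKO (255 to 269.9), at least 236-fold higher, and Spink1 and Ly6d were at least 48.9-fold and 20.8-fold higher. Tff3 had 1 UMI in WT and 3277 in DKO, a ratio of 485 (87.0 to 19165). Outside the lists, and among genes whose level in the class was not below that of the other cells of the library, the highest ratio was that of Cbr3 at 255 CPM in DKO and 0 UMIs in WT (at least 229-fold higher), followed by Sprr1a (at least 82.2-fold) and Pls1 (at least 43.7-fold). Ubd, left out by that rule, had 2 UMIs in WT and 27232 in DKO (ratio 2016, 558 to 16644). H19, Tff3 and Spink1, named as list members, did not meet that rule either. Over all kept DKO cells they stood at 387, 199 and 62.0 CPM, against 262, 180 and 54.5 CPM in the class, so their levels were higher outside it.

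Genes of the canonical and non-canonical NF-kB pathway, which Traf3 restrains through loss of the kinase encoded by Map3k14, had a median of 2.01 (1.19 with 3 members at their bound), and 16 of 24 measured members were higher and 0 lower (14 and 1 relative to the shift). Ccl20 (chromosome 1, 83116766 to 83119167) had no WT UMI and stood at 156 CPM in DKO (150.2 to 162), at least 139.9-fold higher. Over all kept DKO cells Ccl20 stood at 262 CPM, so its level was higher outside the class. Relb and Nfkb2, the subunits of the non-canonical arm, and Lcn2 each had 1 WT UMI, with ratios of 49.4 (8.81 to 1959), 46.9 (8.36 to 1859) and 47.2 (8.41 to 1871). Inflammatory cytokine and chemokine genes had a median of 1.34 (1.18 with 2 at their bound), and 8 of 13 measured members were higher and 0 lower (6 and 2 relative to the shift). Their median was 0.49 with thinned cells and 0.56 at a limit of 10% mitochondrial UMIs, inside the range of random lists. Cxcl10 stood at 1.11 and 25.3 CPM (ratio 22.7, 7.72 to 110.5), and Ccl6 had 0 WT UMIs and was at least 10.7-fold higher. The level that RNA from immune cells would bring was not computed for this list, so such RNA was not separated from a higher level in hepatocyte-like cells. Interferon-stimulated genes had a median of 2.55, and 15 of 21 measured members were higher and 0 lower (13 and 0 relative to the shift). Irf7 stood at 4.08 CPM (2.04 to 7.31) in WT and 142 CPM (137 to 148) in DKO. Ifi44 and Oasl2 had ratios of 63.6 (17.5 to 526) and 95.9 (17.2 to 3794), and Ifi27l2a was at least 12.98-fold higher. Antigen presentation genes had a median of 1.53 (0.93 with 1 at its bound), and 8 of 14 measured members were higher and 0 lower (6 and 1 relative to the shift). Psmb8 stood at 27.1 and 241 CPM, whereas the class I genes B2m and H2-K1 were lower relative to the shift, at -0.59 and -1.02. The class II genes Cd74 and H2-Aa stood at 22.04 and 13.1 CPM in hepatocyte-like cells of DKO. The median class II gene was at 0.409 times the level that RNA from immune cells of that library would bring.

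De novo lipogenesis and lipid droplet genes had a median of 0.79, and 19 of 25 measured members were higher and 0 lower (12 and 1 relative to the shift). The lipid droplet gene Cidec (chromosome 6, 113424634 to 113435760) had 1 WT UMI and 2353 DKO UMIs (129 CPM, ratio 348, 62.5 to 13763), and Cidea was at least 4.74-fold higher. Cd36 stood at 1.49 and 52.4 CPM, Pparg at 11.5 and 89.5 CPM, Thrsp at 275 and 2309 CPM and Dgat2 at 45.3 and 113 CPM. Fasn was higher by 1.004 relative to the shift, whereas Srebf1 and Mlxipl were at -0.82 and -1.09. FoxO and insulin-responsive genes, which insulin signalling represses in part, had a median of -0.66, and 3 of 18 measured members were higher and 4 lower (1 and 5 relative to the shift). G6pc stood at 187 CPM (171 to 204) in WT and 19.2 CPM (17.2 to 21.3) in DKO, with Irs2 and Igfbp1 at -2.70 and -2.61 and Ddit4 at 3.21. Glycolysis genes had a median of 0.51, and 7 of 13 measured members were higher and 0 lower (4 and 0 relative to the shift), with Hk2 at least 4.93-fold and Pfkl 4.84-fold higher. The FoxO median of -0.44 and the glycolysis median of 0.35 when every cell was weighted alike lay inside the range of random lists. Immediate early and heat shock genes had a median of 0.89, and 12 of 22 measured members were higher and 0 lower (9 and 0 relative to the shift). Myc had 0 WT UMIs and was at least 12.9-fold higher, and Ier2 stood at 7.06 and 78.4 CPM. At a limit of 10% mitochondrial UMIs the median of the list was 0.33, inside the range of random lists.

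Oxidative stress response genes had a median of 0.86, and 9 of 15 measured members were higher and 0 lower (7 and 0 relative to the shift). Gpx2 had no WT UMI and was at least 25.5-fold higher, Mt2 stood at 24.9 and 655 CPM, and Ftl1 at 625 CPM (595 to 656) and 11618 CPM (11569 to 11668). Nqo1, a target of the transcription factor Nrf2, stood at 6.68 and 114 CPM. Glutathione transferase genes of the xenobiotic list, picked here as its members with high levels in DKO and not tested as a group, were higher. Gstm1 was at 3257 and 19401 CPM, Gstm2 at 139.6 and 2146 CPM, Gstm3 at 126 and 5818 CPM and Gsta1 at 2.60 and 241 CPM. The split of reads between such near-identical copies is uncertain. Xenobiotic metabolism genes as a list had a median of -1.52, and 8 of 29 measured members were higher and 14 lower (7 and 17 relative to the shift), with Cyp2c54 (-3.13), Cyp2d10 (-2.65), Cyp2c29 (-2.29) and Cyp1a2 (-1.94) among the lower members. The Cyp2c and Cyp2d genes have near-identical copies as well. Hepatocyte secreted protein genes had a median of -1.49, and 2 of 29 measured members were higher and 13 lower (2 and 20 relative to the shift). Alb (chromosome 5, 90460897 to 90476602) stood at 10643 CPM (10520 to 10767) in WT and 1568 CPM (1549.6 to 1586) in DKO, Fgg at 921 and 148 CPM, and Hp, the other way, at 108 and 460.1 CPM. The 99 WT cells of cluster 19 held 75.1% of the Alb UMIs of the WT class, and 12.5% of their UMIs were of the secreted protein list, against 1.51% in the other WT and 2.04% in the other DKO hepatocyte-like cells. Outside cluster 19 Alb stood at 3421 CPM in WT and 1555 CPM in DKO. Without cluster 19 the secreted median was 0.064 and the xenobiotic median -0.056. Under the same rule the lowest ratios were those of the major urinary protein genes Mup7 (1516 and 26.0 CPM), Mup1, Mup14 and Mup12, whose reads are shared among copies, and of Hsd3b5 (-4.47), Slco1a1 (-4.20) and C8b (-4.08). Outside cluster 19 Mup7 stood at 338.9 and 20.8 CPM. A difference in sex between the mice of the libraries was not tested as a source of these low ratios. Values of Xist and Y-linked genes, left out of the named genes, are not given here.

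Periportal zonation genes had a median of -1.17, and 3 of 16 measured members were higher and 7 lower (2 and 8 relative to the shift), led by Ctsc (-2.69), Etnppl (-2.62) and Hsd17b6 (-2.40), with Aldh1b1 higher (2.09). The periportal median of -0.50 without cluster 19 lay inside the range of random lists. Pericentral zonation genes had a median of -0.46, and 4 of 16 measured members were higher and 3 lower (2 and 5 relative to the shift). Their median was 0.093 with thinned cells. Within that list Glul stood at 180.5 CPM (165 to 197) in WT and 1235 CPM (1219 to 1251) in DKO, and Cyp7a1 at 3.34 and 33.5 CPM. Bile acid synthesis and transport genes had a median of -0.72 (-0.19 without cluster 19), and 3 of 21 measured members were higher and 7 lower (2 and 9 relative to the shift), with Cyp7b1 at 92.5 and 16.8 CPM. Urea cycle and amino acid catabolism genes had a median of -0.56, and 5 of 22 measured members were higher and 1 lower (3 and 5 relative to the shift). The urea cycle median of -0.44 at a limit of 25% mitochondrial UMIs lay inside the range of random lists. Endoplasmic reticulum stress genes had a median of -0.76, and 3 of 16 measured members were higher and 3 lower (3 and 6 relative to the shift). That median was 0.57 without cluster 19, 0.13 with thinned cells and 0.079 with cells weighted alike. Hspa5 stood at 196 and 60.4 CPM and turned to 0.18 relative to the shift without cluster 19, whereas Ddit3, Chac1 and Asns were higher (2.32, 2.93 and 1.33). The list of continuous and capillarised endothelial genes had a median of 2.74 in hepatocyte-like cells, and 6 of 9 measured members were higher and 0 lower (5 and 0 relative to the shift). Its leading members Col4a1 (6.14), Spp1 (3.88), Ly6a (3.49) and Ly6c1 (2.82) encode a basement membrane collagen, a matrix protein and surface proteins of the Ly6 family, none made by endothelial cells alone. The medians of the remaining 11 lists lay inside the range of random lists. These were TGF-beta and fibrosis (1.15), lipid-associated macrophage (0.60), YAP and TAZ target (0.46), biliary identity (0.38), naive and resident lymphocyte (0.19) and hepatocyte identity transcription factor genes (0.069). The others were Notch pathway (0.055), acute phase (-0.21), fatty acid oxidation (-0.30), liver sinusoidal endothelial (-0.32, but low under 10 alternatives, at -0.32 to -1.67) and cholesterol synthesis genes (-0.34). Without cluster 19 the acute phase median turned to 1.08 and left that range. Hnf4a stood at 553 and 535 CPM and Cebpb at 44.9 and 255 CPM.

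**Figure D3:**
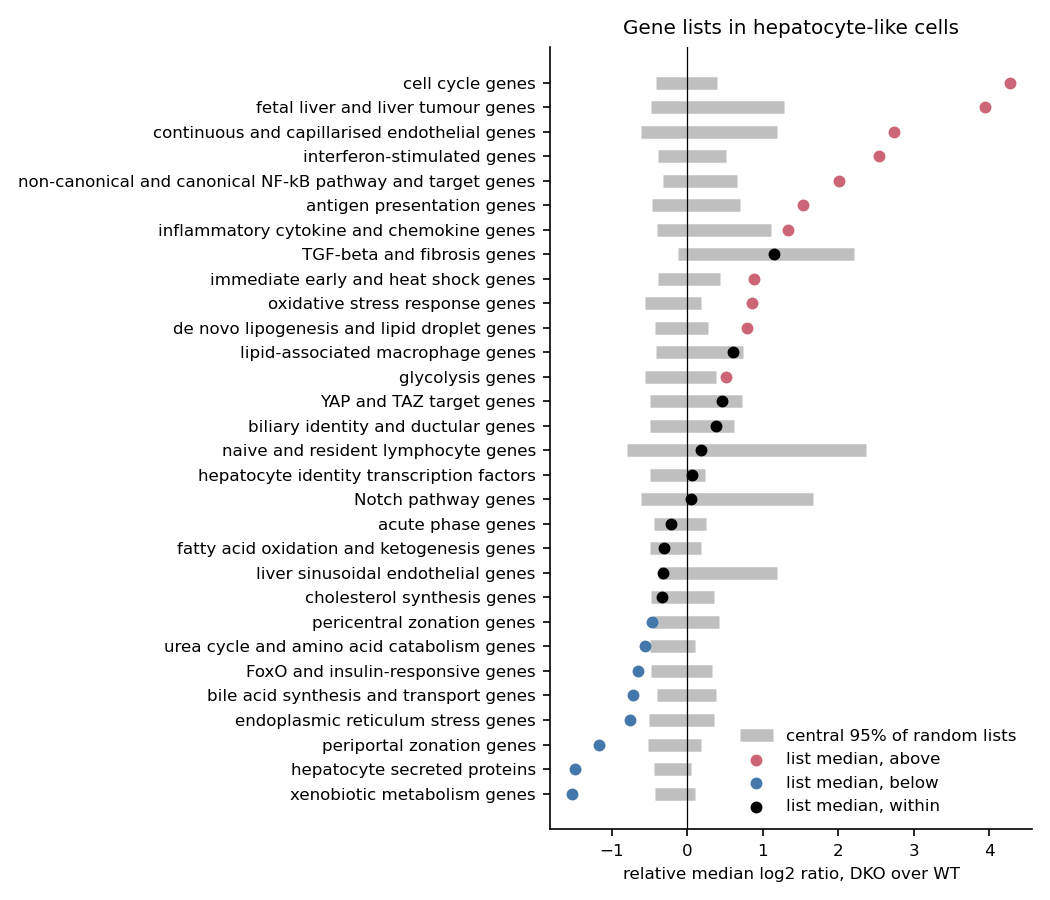
Median log2 ratio (DKO over WT) of each gene list in hepatocyte-like cells, relative to the median of all measured genes; grey bars span the central 95% of 10000 random lists of like expression, with list medians above (red), below (blue) or within (black) that span. Cell cycle genes had the highest median (4.28) and xenobiotic metabolism genes the lowest (-1.52).

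**Figure D4:**
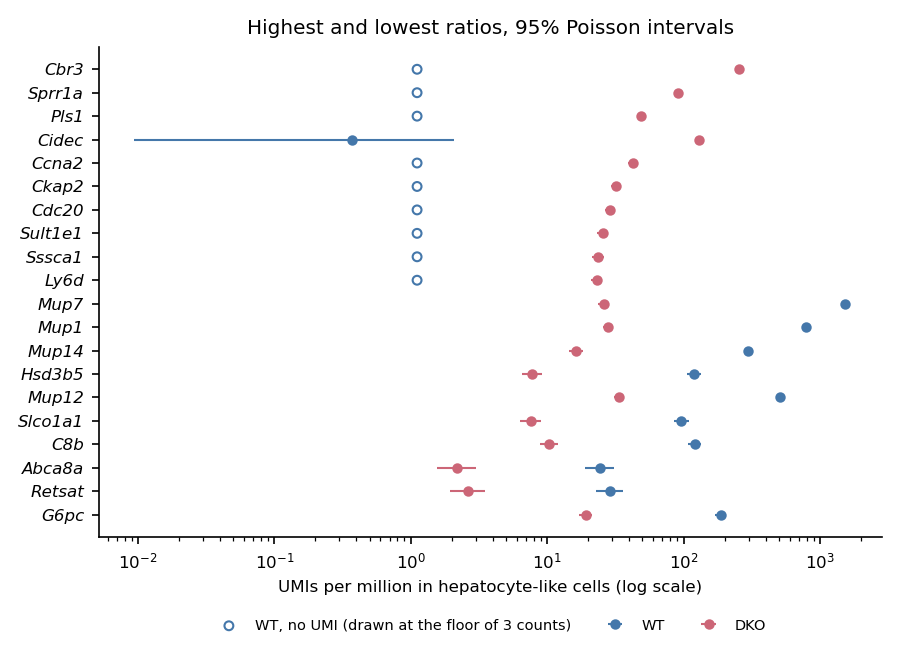
Levels (CPM, logarithmic axis) of the 10 genes with the highest and the 10 with the lowest ratios in hepatocyte-like cells of the WT (blue) and DKO (red) libraries. Bars are exact 95% Poisson intervals, and a count of 0 is drawn at the level of 3 UMIs. Mup7 stood at 1516 CPM in WT and 26.0 CPM in DKO.

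The comparison over all kept cells asked what differed in the tissue as sampled, with cell type shares and transcript levels together (median log2 ratio of all genes 0.33). Sinusoidal endothelial, stellate cell quiescence and cytotoxic lymphocyte genes were lower in DKO, and cell cycle, oxidative stress, interferon, lipid and NF-kB genes were higher. Of 33 lists, 8 had a median above and 14 a median below the central 95% of random lists. Liver sinusoidal endothelial genes had a median of -3.57, and 0 of 19 measured members were higher and 16 lower (0 and 17 relative to the shift). Dnase1l3 stood at 769.6 CPM (741 to 799) in WT and 17.6 CPM (15.9 to 19.3) in DKO, Oit3 at 126 and 2.91 CPM and Kdr at 293 and 10.5 CPM. Continuous endothelial genes had a median of -1.997, and 3 of 16 measured members were higher and 9 lower (3 and 10 relative to the shift), with Pecam1 at 119 and 10.8 CPM. Tek, Btnl9, Robo4, Clec14a, Adgrf5, Cyp4b1 and Npr1 were among the 10 genes with the lowest ratios, at -5.39 to -6.10. Stellate cell quiescence genes had a median of -3.07, and 2 of 9 measured members were higher and 5 lower (2 and 7 relative to the shift), with Colec11 and Reln at -4.57 and -4.42 and Rbp1 the other way at 3.37. Mesenchymal marker UMIs as a sum were higher in DKO (121.3 and 185.8 CPM, ratio 1.53, 1.39 to 1.70). The median log2 ratio of these markers before the shift was taken off was 0.21, below that shift of 0.33. One of them, Rgs5, was among the leading genes of unnamed cluster 4, so the sum does not count mesenchymal cells. Cytotoxicity genes had a median of -1.32, and 0 of 14 measured members were higher and 7 lower (0 and 8 relative to the shift), with Ifng (-3.31), Gzma (-2.51) and Gzmb (-2.26). The markers of natural killer or innate lymphoid cells, some of them in that list, had a median log2 ratio of -1.48 before the shift was taken off. Their UMIs as a sum went the other way (178.5 and 217.0 CPM, ratio 1.22, 1.12 to 1.32). T cell exhaustion and regulatory genes (-0.90, 1 of 13 higher and 2 lower, or 0 and 6 relative to the shift) and naive and resident lymphocyte genes (-0.94, 0 of 13 higher and 3 lower, or 0 and 6 relative to the shift) were also low. Lipid-associated macrophage genes had a median of 0.69, and 9 of 18 measured members were higher and 0 lower (7 and 1 relative to the shift), with Trem2 at 0.844 and 10.1 CPM and Ms4a7 at 1.41 and 16.1 CPM. That median was 0.42 when 500 genes were required. At a limit of 25% mitochondrial UMIs those of exhaustion (-0.28) and naive lymphocyte genes (-0.11) lay inside the range of random lists. At a limit of 10% mitochondrial UMIs, which left 125 WT and 6971 DKO cells and only 2 WT cells outside the hepatocyte-like class, the medians of the endothelial and lymphocyte lists turned positive.

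The gene with the highest ratio among those seen in both libraries was the ubiquitin-like gene Ubd, with 2 UMIs in WT and 35670 in DKO (1502 CPM, ratio 2668, 738 to 22029). H19, Ccl20, Sprr1a, Guca2b, Apela, Gipc2 and Spink1 had no UMI in any kept WT cell and were at least 458-fold, 311-fold, 100.9-fold, 87.5-fold, 80.0-fold, 79.4-fold and 73.4-fold higher. Cell cycle genes had a median of 2.02, and 17 of 24 measured members were higher and 0 lower (14 and 0 relative to the shift), with Cdk1 at 6.47 and 52.6 CPM and Cdkn1a at 8.16 and 83.3 CPM. Medians were also high for oxidative stress (1.18, 9 of 16 higher and 1 lower, or 9 and 1 relative to the shift), interferon-stimulated (1.16, 13 of 21 higher and 1 lower, or 11 and 2 relative to the shift) and lipogenesis genes (1.12, 18 of 25 higher and 0 lower, or 13 and 0 relative to the shift). NF-kB genes (0.56, 12 of 26 higher and 0 lower, or 10 and 2 relative to the shift), fetal liver genes (0.78, 5 of 12 higher and 0 lower, or 5 and 1 relative to the shift) and hepatocyte identity transcription factors (0.40, 8 of 19 higher and 0 lower, or 3 and 0 relative to the shift) were high as well. The median of hepatocyte identity genes at a limit of 25% mitochondrial UMIs (0.28) and that of fetal liver genes with no limit (0.66) lay inside the range of random lists. Hepatocyte lists that were low over all kept cells were xenobiotic (-1.22, 8 of 29 higher and 13 lower, or 7 and 17 relative to the shift), secreted protein (-1.04, 2 of 29 higher and 11 lower, or 2 and 17 relative to the shift) and bile acid genes (-0.78, 3 of 21 higher and 7 lower, or 1 and 10 relative to the shift). Periportal (-0.59, 3 of 16 higher and 3 lower, or 3 and 6 relative to the shift) and FoxO genes (-0.47, 2 of 18 higher and 3 lower, or 1 and 6 relative to the shift) were low as well. Endoplasmic reticulum stress (-0.47, 3 of 16 higher and 2 lower, or 3 and 3 relative to the shift) and urea cycle genes (-0.26, 5 of 22 higher and 1 lower, or 5 and 2 relative to the shift) had medians below the range of random lists with members going both ways, and the urea cycle median before the shift was taken off was 0.069. Without cluster 19 the xenobiotic and secreted protein medians were 0.39 and 0.61. The medians of bile acid (-0.045), periportal (-0.045) and endoplasmic reticulum stress genes (-0.18) without that cluster lay inside the range of random lists, as did FoxO (-0.42) and urea cycle genes (-0.22) when 500 genes were required. Antigen presentation genes were low here (-0.43, 2 of 18 higher and 0 lower, or 2 and 1 relative to the shift), with Psmb8 higher (2.102), and their median was 2.45 at a limit of 10% mitochondrial UMIs. The other 11 lists lay inside the range of random lists, with medians of -0.53 for Notch pathway, -0.31 for immediate early, -0.27 for pericentral, -0.22 for inflammatory cytokine and -0.052 for YAP and TAZ target genes. Acute phase (-0.021), fatty acid oxidation (-0.012), cholesterol synthesis (0.027), biliary identity (0.17), glycolysis (0.31) and TGF-beta and fibrosis genes (0.52) completed these.

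B cell-like (53 WT and 169 DKO cells) and T cell-like cells (62 and 155), outside the target of the knockout, were compared in the same way, with shifts of 0.38 and 0.31. Immediate early and heat shock genes, as 1 list, were lower in B cell-like cells and cytotoxicity genes lower in T cell-like cells of DKO, but each call ended under an alternative given below. Xenobiotic, urea cycle, secreted protein and oxidative stress genes were higher in both classes. Gstm1, a hepatocyte gene, was found in 5.66% of B cell-like cells in WT and 68.0% in DKO and in 4.84% and 72.9% of T cell-like cells, at median depths of 842 and 1210 UMIs and 1079 and 1648 UMIs. Its level in DKO was 3108 CPM in B cell-like and 3904 CPM in T cell-like cells, against 19401 CPM in hepatocyte-like cells. Alb stood at 339.5 CPM in WT and 286.9 CPM in DKO in B cell-like cells, and at 165.7 and 348.7 CPM in T cell-like cells. In hepatocyte-like cells Alb was itself lower in DKO (10643 and 1568 CPM). Its levels in lymphocyte-like cells therefore do not compare the amount of hepatocyte RNA between the libraries. Transcripts of hepatocytes in these classes are not read as made by lymphocytes, and free RNA and doublets were not separated as their origin. In B cell-like cells the high lists were xenobiotic (1.92, 1.403 with members at 0 at their bound), urea cycle (1.16, 0.83), secreted protein (1.09, 0.80) and oxidative stress genes (0.96, 0.74). With members at 0 at their bound, the oxidative stress median lay inside the range of random lists (-0.46 to 0.87). Immediate early and heat shock genes had a median of -0.83 in B cell-like cells (-0.19 with no minimum count), and 3 of 17 measured members were higher and 6 lower (2 and 6 relative to the shift). The secreted protein median with no limit on mitochondrial UMIs (0.34) lay inside the range of random lists, as did the urea cycle (1.24) and oxidative stress medians (0.58) with thinned cells. The oxidative stress call also ended with every cell weighted alike (0.67) and against lists matched on GC content. Hspa1b stood at 4095 CPM (3538 to 4716) in WT and 570.1 CPM (484 to 667) in DKO, Hspa1a at 1592 and 272 CPM and Myc at 403 and 65.4 CPM. Retnla had 0 UMIs in WT and 520 in DKO (at least 29.7-fold higher), and S100a6 and Crip1 were at least 7.70-fold and 6.27-fold higher. Haemoglobin genes were high in B cell-like cells of DKO too, with Hba-a1, which has a near-identical copy, at 1256 CPM and 0 WT UMIs. Sell (-1.30) and Malat1 (-1.91) were lower. The lists inside the range of random lists were NF-kB (0.28), FoxO (0.095), glycolysis (0.60), fatty acid oxidation (0.45), periportal (1.16), antigen presentation (0.15), naive and resident lymphocyte (-0.95) and endoplasmic reticulum stress genes (-0.31).

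In T cell-like cells, cytotoxicity genes had a median of -0.69 (-0.53 with every cell weighted alike, inside the range of random lists), and 1 of 14 measured members were higher and 4 lower (0 and 4 relative to the shift). Gzma stood at 1657 CPM (1385 to 1968) in WT and 604 CPM (520.4 to 697) in DKO, Gzmb at 803 and 339 CPM, Ifng at 319 and 64.6 CPM and Ccl4 at 688 and 139 CPM. No cluster was named as natural killer cells, and their share inside the class was not measured, so it was not separated from lower levels per cell. Xcl1, Satb1 and Ptprc were lower (-1.61, -1.65 and -1.47), and Rps19, Ppp1ca, Rplp1 and Tmsb10 higher (3.64, 2.01, 1.94 and 1.88), in T cell-like cells of DKO. Rps19 and Rplp1 were higher in B cell-like cells too (3.12 and 3.21), so these were not particular to T cell-like cells. The high lists were xenobiotic (3.44, 3.18 with members at 0 at their bound), lipogenesis (3.33, 0.71), secreted protein (2.91, 1.91), periportal (2.65, 2.34) and urea cycle genes (2.197, 2.15). Fatty acid oxidation (2.05, 1.10), lipid-associated macrophage (1.65, no member at 0), oxidative stress (1.63, 1.45) and FoxO genes (1.54, 0.57) were high as well. With members at 0 at their bound, the lipogenesis and FoxO medians lay inside the range of random lists (-0.54 to 1.55 and -0.83 to 1.20). Of the 7 measured lipogenesis members, 5 were at 0. Thrsp and Scd1, liver lipogenesis genes, had 0 WT UMIs and 106 and 104 DKO UMIs. The FoxO median fell inside the range of random lists under 6 alternatives (0.21 to 1.26), and the lipid-associated macrophage median under 2 (0.44 and 0.21). Inside the range of random lists lay interferon-stimulated (0.78), NF-kB (0.27), glycolysis (-0.029), antigen presentation (-0.21) and naive and resident lymphocyte genes (-0.22). Immediate early (-0.31), T cell exhaustion and regulatory (-0.57), cell cycle (-0.59) and endoplasmic reticulum stress genes (-0.77) did so too.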

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

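Tests at the 10% mitochondrial limit and without cluster 19 were chosen only after the data were seen, but their bounds were written before the tests were run. The 25% limit was an alternative fixed beforehand, with its bounds written afterwards. Tests of class I and class II genes apart, of the rise over WT, and of endothelial cells placed elsewhere or lost through a lower yield were chosen only after the result was seen. Several list medians lay outside the range of random lists in opposite directions in hepatocyte-like and lymphocyte-like cells, and the difference between classes was not tested. Transcripts of hepatocytes in lymphocyte-like cells are not read as made there, with Gstm1 in 4.84% of WT and 72.9% of DKO T cell-like cells. The medians of hepatocyte lists are therefore not read as opposite regulation by cell type. Without cluster 19 the secreted protein median of hepatocyte-like cells turned, and the xenobiotic, FoxO and periportal medians lost their call. Against B cell-like cells, the relative medians were -1.49 and 1.09 for secreted proteins, -1.52 and 1.92 for xenobiotic metabolism, -0.56 and 1.16 for urea cycle genes, and 0.89 and -0.83 for immediate early and heat shock genes. Against T cell-like cells, they were -1.49 and 2.91 for secreted proteins, -0.66 and 1.54 for FoxO genes, -1.52 and 3.44 for xenobiotic metabolism, -0.56 and 2.197 for urea cycle genes and -1.17 and 2.65 for periportal genes. Barcodes left out by the cell filter, which no comparison used, also held transcripts that mark the DKO library. The 1617 DKO barcodes left out held 290 UMIs of H19, 121 of Ccl20 and 115 of Cbr3, and the 11964 WT barcodes left out held 0, 0 and 1.

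Secreted protein genes were lower in hepatocyte-like cells of DKO (median -1.49). A GC content bias is argued against, since the median after a GC correction was -1.67, and so is an effect of WT cells with 25% to 50% mitochondrial UMIs, since it was -1.68 at a limit of 25%. Without the Mup- and Alb-rich cluster 19 the median was 0.064, so the pattern of the list rested on that cluster. Alb, the list member looked up there, stayed lower in DKO outside it (3421 and 1555 CPM), and levels of the other members outside it are not given here. The list members Alb, Fgg, Fga and Fgb are among the leading genes of cluster 19, which held 99 WT and 14 DKO cells. Its removal was therefore bound to raise the median, and only the size of the change is informative, not the cause. At a limit of 10% the median was -0.15, which met the bound set beforehand for damaged WT cells as the source, but that limit also removed 96 of the 99 cluster 19 cells, so damage and cluster 19 cannot be told apart there. Whether DKO hepatocytes lack cells like cluster 19 because of the genotype, or whether such cells were lost in handling, stays open and untested.

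Interferon-stimulated and antigen presentation genes were higher in hepatocyte-like cells of DKO. The level of 12 immune genes there was 1.52% of that in the 754 immune cells of the library, and interferon-stimulated genes stood at a median of 27.2 times the level that such immune RNA would bring. Since WT already stood at a median of 2.63 times that level once carried by the shift, the rise over WT was set against it too. The median rise was 16.6 times that level, which argues against free RNA or doublets of immune cells as the source for interferon-stimulated genes as a list, and a median of 2.096 at a limit of 10% mitochondrial UMIs argues against damaged WT cells. For all antigen presentation genes the level was 2.11 times that of immune RNA, between the bounds set for either outcome, so their sources cannot be told apart as a list. Class I genes stood at 7.69 times that level in DKO, but at 6.04 times in WT, so this level says nothing of a rise. Their median rise was 1.98 times that level (0.701 to 2.69), with B2m and H2-K1 below the shift and Psmb8 and Psmb9 above it, so the sources of any rise cannot be told apart for class I genes. Class II genes stood at 0.409 times that level, which is consistent with immune RNA as their source. The genotype and any other difference between the mice behind each library stay open for the interferon-stimulated genes.

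The endothelial-like share was lower in DKO (0.224% against 9.85%). Endothelial cells that kept their markers but were placed in other clusters are argued against as the whole source by the marker UMIs over all kept cells, whose ratio was 0.0648. Removal of such cells by the cell filter is argued against by the ratio over all barcodes, 0.0494 per non-mitochondrial UMI. Both ratios would also fall with lower levels of these markers per endothelial cell, so they do not count cells. Cluster 17, which had endothelial markers up, held 25 WT and 116 DKO cells, against 19 DKO cells in the class. With cluster 17 placed in the class the share ratio was 0.147 instead of 0.0228, so cells left unnamed account for part of the size of the share difference but leave its direction. A lower yield of all non-hepatocyte cells is argued against by the other classes, the lowest of which, neutrophil-like cells, had a share ratio of 0.252 (0.148 to 0.428), and by the neutrophil marker UMIs, whose ratio over all kept cells was 0.450 against 0.0648. A loss of endothelial cells alone during dissociation and lower marker levels per endothelial cell were not tested. Both stay open, as does the genotype.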

How the results depend on the processing

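The limit of 10% mitochondrial UMIs, the removal of cluster 19, clusters 4 and 17 placed in a class, and random lists matched on GC content were chosen only after the results were seen. In hepatocyte-like cells 8 of 19 called lists kept their direction and their side of the threshold under each alternative that gave a value: cell cycle, fetal liver, NF-kB, interferon-stimulated, antigen presentation, oxidative stress, lipogenesis and continuous endothelial genes. Of 284 values of the called lists there, 242 kept the call, 37 lost it and 5 reversed, with the 3 scalings not counted because they leave relative medians as they are. Over all kept cells 6 of 22 called lists kept it everywhere, and of 219 values 181 kept it, 26 lost it and 12 reversed. Values below are relative median log2 ratios with the reported value after "from", and unless stated the cause was not tested.

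Removing cluster 19 (99 WT and 14 DKO cells) reversed, in hepatocyte-like cells, hepatocyte secreted proteins 0.064 (from -1.49) and endoplasmic reticulum stress 0.57 (from -0.76) and Hspa5 0.18 (from -2.23), and ended the calls of FoxO and insulin-responsive -0.46 (from -0.66), bile acid synthesis and transport -0.19 (from -0.72), xenobiotic metabolism -0.056 (from -1.52), pericentral zonation -0.23 (from -0.46) and periportal zonation -0.50 (from -1.17). Over all kept cells it reversed hepatocyte secreted proteins 0.61 (from -1.04) and xenobiotic metabolism 0.39 (from -1.22) and Fga 0.41 (from -2.38), and ended fetal liver and liver tumour 0.63 (from 0.78), bile acid synthesis and transport -0.045 (from -0.78), periportal zonation -0.045 (from -0.59) and endoplasmic reticulum stress -0.18 (from -0.47). Fetal liver genes moved little and lay just inside the range, and pericentral genes lost their call under most other alternatives too, so these 2 do not rest on cluster 19 alone.

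At a limit of 10% mitochondrial UMIs, 123 WT hepatocyte-like cells and 2 other WT cells were left, so over all kept cells the alternative compares WT hepatocyte-like cells with all DKO cells. It reversed hepatocyte identity transcription factors -0.20 (from 0.40), liver sinusoidal endothelial 0.14 (from -3.57), continuous and capillarised endothelial 0.99 (from -1.997), antigen presentation 2.45 (from -0.43), T cell exhaustion and regulatory 0.98 (from -0.90), cytotoxicity 1.91 (from -1.32), naive and resident lymphocyte 0.99 (from -0.94) and endoplasmic reticulum stress 0.26 (from -0.47), with Pecam1 2.46 (from -3.79), Gzma 2.56 (from -2.51), Gzmb 1.28 (from -2.26), Hsp90b1 0.78 (from -1.48), Itga1 0.99 (from -3.47) and Cd69 0.85 (from -1.54), and ended hepatocyte secreted proteins -0.26 (from -1.04), bile acid synthesis and transport -0.20 (from -0.78), xenobiotic metabolism -0.31 (from -1.22) and periportal zonation -0.38 (from -0.59). In hepatocyte-like cells it reversed Abca8a 0.88 (from -4.00) and Hspa5 0.17 (from -2.23) and ended hepatocyte secreted proteins -0.15 (from -1.49), FoxO and insulin-responsive -0.54 (from -0.66), bile acid synthesis and transport -0.16 (from -0.72), xenobiotic metabolism -0.12 (from -1.52), pericentral zonation -0.19 (from -0.46), periportal zonation -0.40 (from -1.17), inflammatory cytokine and chemokine 0.56 (from 1.34), immediate early and heat shock 0.33 (from 0.89) and endoplasmic reticulum stress -0.045 (from -0.76). The secreted protein, bile acid, xenobiotic and periportal calls thus ended within the class as well, where the make-up of WT cells by class plays no part. That limit also removed 96 of the 99 WT cells of cluster 19, so the make-up of WT cells within the class was not set apart. A limit of 25% ended, over all kept cells, hepatocyte identity transcription factors 0.28 (from 0.40), fetal liver and liver tumour 0.70 (from 0.78), antigen presentation -0.17 (from -0.43), T cell exhaustion and regulatory -0.28 (from -0.90) and naive and resident lymphocyte -0.11 (from -0.94), reversed Prf1 0.10 (from -1.81) and Cd69 2.32 (from -1.54), and in hepatocyte-like cells ended urea cycle and amino acid catabolism -0.44 (from -0.56) and pericentral zonation -0.18 (from -0.46). With no limit the calls of fetal liver and liver tumour 0.66 (from 0.78) over all kept cells and of pericentral zonation -0.17 (from -0.46) in hepatocyte-like cells ended. With 500 genes or more, those of FoxO and insulin-responsive -0.42 (from -0.47), urea cycle and amino acid catabolism -0.22 (from -0.26), lipid-associated macrophage 0.42 (from 0.69) and naive and resident lymphocyte -0.45 (from -0.94) ended over all kept cells and that of pericentral zonation -0.40 (from -0.46) in hepatocyte-like cells.

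Weighting every cell alike reversed, over all kept cells, hepatocyte secreted proteins 0.12 (from -1.04) and xenobiotic metabolism 0.021 (from -1.22) and ended hepatocyte identity transcription factors 0.32 (from 0.40), FoxO and insulin-responsive -0.33 (from -0.47), bile acid synthesis and transport -0.27 (from -0.78), antigen presentation -0.14 (from -0.43), T cell exhaustion and regulatory -0.60 (from -0.90) and endoplasmic reticulum stress -0.18 (from -0.47). In hepatocyte-like cells it reversed endoplasmic reticulum stress 0.079 (from -0.76) and ended hepatocyte secreted proteins -0.24 (from -1.49), FoxO and insulin-responsive -0.44 (from -0.66), glycolysis 0.35 (from 0.51), bile acid synthesis and transport -0.20 (from -0.72), xenobiotic metabolism -0.24 (from -1.52) and pericentral zonation -0.052 (from -0.46). Thinning hepatocyte-like cells to 400 UMIs reversed pericentral zonation 0.093 (from -0.46) and endoplasmic reticulum stress 0.13 (from -0.76) and ended hepatocyte secreted proteins -0.16 (from -1.49), glycolysis 0.38 (from 0.51), bile acid synthesis and transport -0.29 (from -0.72), xenobiotic metabolism -0.15 (from -1.52) and inflammatory cytokine and chemokine 0.49 (from 1.34). Keeping called doublets, which altered the clusters, ended urea cycle and amino acid catabolism -0.45 (from -0.56) and pericentral zonation -0.13 (from -0.46), resolution 0.5 ended urea cycle and amino acid catabolism -0.44 (from -0.56) and pericentral zonation -0.37 (from -0.46), and clustering each library alone ended glycolysis 0.35 (from 0.51) and pericentral zonation -0.43 (from -0.46). With no minimum count pericentral zonation -0.28 (from -0.46) ended in hepatocyte-like cells, and with a minimum of 50 fetal liver and liver tumour 0.54 (from 0.78) ended over all kept cells. Against random lists matched on GC content as well, hepatocyte identity transcription factors 0.40 (from 0.40) over all kept cells and glycolysis 0.51 (from 0.51) in hepatocyte-like cells lay inside the range.

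In B cell-like cells 1 of 5 called lists kept its call everywhere, xenobiotic metabolism, and in T cell-like cells 7 of 10. Members at 0 set to their bound were not among these alternatives. Under that bound the lipogenesis median of T cell-like cells (0.71) lay inside the range of random lists. Calls of B cell-like cells that ended were hepatocyte secreted proteins 0.34 (from 1.09) with no mitochondrial limit, oxidative stress response 0.67 (from 0.96) with cells weighted alike, urea cycle and amino acid catabolism 1.24 (from 1.16) and oxidative stress response 0.58 (from 0.96) with thinned cells, oxidative stress response 0.96 (from 0.96) against lists matched on GC content and immediate early and heat shock -0.19 (from -0.83) with no minimum count. Calls of T cell-like cells that ended were FoxO and insulin-responsive 0.80 (from 1.54) and lipid-associated macrophage 0.44 (from 1.65) at a limit of 25%, FoxO and insulin-responsive 0.56 (from 1.54) with no limit, FoxO and insulin-responsive 1.26 (from 1.54) with 500 genes or more, FoxO and insulin-responsive 0.43 (from 1.54) at resolution 2, FoxO and insulin-responsive 0.60 (from 1.54) with each library clustered alone, FoxO and insulin-responsive 0.21 (from 1.54) and lipid-associated macrophage 0.21 (from 1.65) with no minimum count and cytotoxicity -0.53 (from -0.69) with cells weighted alike.

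Lists inside the range of random lists as reported that left it under an alternative were, in hepatocyte-like cells, YAP and TAZ target (from 0.46) 0.58 (25%), 1.14 (thinned), liver sinusoidal endothelial (from -0.32) -0.58 (25%), -1.26 (no limit), -0.68 (500 genes), -1.57 (doublets kept), -1.67 (clustered alone), -0.38 (cluster 4 inside), -0.58 (mean over cells), -0.71 (no minimum), -0.54 (minimum of 50), -0.32 (GC-matched), acute phase (from -0.21) -0.47 (500 genes), 1.17 (10%), 1.08 (no cluster 19), 0.76 (mean over cells), 0.86 (thinned), TGF-beta and fibrosis (from 1.15) 1.92 (500 genes), 1.43 (10%), 0.81 (no minimum) and lipid-associated macrophage (from 0.60) 0.84 (10%), 1.46 (no cluster 19), 1.16 (mean over cells). Over all kept cells they were pericentral zonation (from -0.27) -0.50 (25%), TGF-beta and fibrosis (from 0.52) 0.85 (25%), 0.81 (no limit), 0.85 (10%), 0.67 (no minimum), inflammatory cytokine and chemokine (from -0.22) -0.71 (no limit), 1.93 (10%), -0.75 (mean over cells), immediate early and heat shock (from -0.31) -0.38 (no limit), -0.39 (500 genes), 1.47 (10%), -0.43 (no cluster 19), -0.49 (mean over cells), -0.31 (GC-matched), Notch pathway (from -0.53) -0.58 (500 genes), -0.63 (no cluster 19), -0.70 (mean over cells), -0.72 (no minimum), -0.98 (minimum of 50), biliary identity and ductular (from 0.17) 1.09 (10%), fatty acid oxidation and ketogenesis (from -0.012) -0.65 (10%) and acute phase (from -0.021) 1.10 (10%), 1.396 (no cluster 19), 0.88 (mean over cells). In B cell-like cells they were naive and resident lymphocyte (from -0.95) -0.90 (no limit), -0.79 (no minimum), -0.87 (thinned), glycolysis (from 0.60) 0.59 (doublets kept), periportal zonation (from 1.16) 1.26 (doublets kept), 1.51 (no minimum), 1.16 (GC-matched) and endoplasmic reticulum stress (from -0.31) -0.84 (doublets kept), and in T cell-like cells cell cycle (from -0.59) -1.39 (25%), -1.02 (500 genes), interferon-stimulated (from 0.78) 0.95 (no limit) and endoplasmic reticulum stress (from -0.77) -0.90 (no limit), -1.19 (500 genes), -0.79 (doublets kept), -0.85 (resolution 2), -0.53 (no minimum).

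The log2 ratio of Pten in hepatocyte-like cells, -0.81 as reported and not relative to the shift, was -0.92 at a limit of 25%, -0.18 with no limit, -1.31 at 10% and -1.07 without cluster 19. It was -1.24 with TMM factors, -1.26 with DESeq2 size factors and -1.17 with the total without mitochondrial and haemoglobin genes, which take off most of the shift. With cells weighted alike the values were Pten -0.91 and Traf3 -0.47, and with thinned cells Pten -0.91 and Traf3 -0.63. Over all kept cells the value of Pten (-0.61) was -0.77 at a limit of 25%, -0.065 with no limit, -1.27 at 10%, -0.79 without cluster 19, -0.84 with TMM factors, -0.86 with DESeq2 size factors and -0.71 with cells weighted alike. With the total without mitochondrial and haemoglobin genes it was -0.98 and Traf3 -0.36 (from 0.005).

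A ratio of class shares, DKO over WT, counted as reversed only if its reported interval excluded 1 and the ratio then crossed 1. The B cell, plasmacytoid dendritic cell, mesenchymal and hepatocyte intervals included 1, so their crossings of 1 are not counted here. Ratios reversed for Kupffer cell 1.72 (from 0.463) with no mitochondrial limit, Kupffer cell 1.71 (from 0.463) at resolution 0.5, Kupffer cell 1.67 (from 0.463) at resolution 2, Kupffer cell 1.67 (from 0.463) and monocyte or infiltrating macrophage 0.786 (from 4.54) with each library clustered alone, neutrophil 1.25 (from 0.252) with 500 genes or more and T cell 1.04 (from 0.717) at a limit of 25%. Ratios that moved beyond their interval were B cell 2.57 (from 0.914), Kupffer cell 0.225 (from 0.463), conventional dendritic cell 0.320 (from 0.680), endothelial 0.050 (from 0.0228), hepatocyte 1.12 (from 0.985), monocyte or infiltrating macrophage 2.12 (from 4.54) and plasmacytoid dendritic cell 0.878 (from 2.01) with 500 genes or more, endothelial 0.0860 (from 0.0228) with each library clustered alone, B cell 3.83 (from 0.914) and hepatocyte 0.880 (from 0.985) at a limit of 25% and hepatocyte 0.692 (from 0.985) at resolution 0.5. With cluster 4 inside its class the ratio was hepatocyte 1.09 (from 0.985), and with cluster 17 inside its class endothelial 0.147 (from 0.0228). Shares were not computed at a limit of 10%.

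Of the lists of B cell-like cells 103 values kept their side, 8 entered and 6 left a call, and of those of T cell-like cells 189 kept it, 8 entered and 9 left. Of the named genes, 103 over all kept cells gave 563 values inside and 155 beyond their counting interval and 9 reversed, and 91 in hepatocyte-like cells gave 903, 192 and 3. For the 41 named genes of B cell-like cells 10 of 293 values lay beyond the interval and 0 reversed, and for the 57 of T cell-like cells 35 of 519 and 0. With other minimum counts 16 and 16 of the 20 highest and lowest genes were shared over all kept cells, 20 and 18 in hepatocyte-like cells, 8 and 6 in B cell-like cells and 0 and 9 in T cell-like cells, so which genes are extreme in lymphocyte-like cells depends on the minimum. B cell-like cells gave no value at a limit of 25% (4 WT cells), at 10% (0) or with 500 genes or more (8), and T cell-like cells none at 10% (0). Depth limits the lymphocyte-like comparisons, where the exact interval for a count of 0 in WT reaches 78.3 CPM in B cell-like and 47.0 CPM in T cell-like cells. No paired analysis was possible because nothing in the labels pairs the libraries.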

Other observations

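The tests of the correlation with GC content were chosen only after the result was seen, and the cells and genes in the next paragraphs were looked up after their values were seen. Cluster 4, which stayed unnamed, held 696 DKO cells and 4 WT cells, and its leading genes were Ccl20, H19, Rgs5, Fabp6, Spp1, Guca2b, Mfge8, Rbp1, Sox4 and Chmp4c. An Alb UMI was found in 86.4% of its DKO cells, in 82.7% of the hepatocyte-like and in 24.0% of the immune cells of that library, at median depths of 1950, 1658 and 1979 UMIs. Cps1 stood at 62.9 CPM in cluster 4 and 327.4 CPM in hepatocyte-like cells of DKO, and Sox9 at 90.7 and 33.6 CPM. Of the biliary genes looked up, Spp1 stood at 223.2 and 19.7 CPM, Sox4 at 181.98 and 26.3 CPM, Tm4sf4 at 20.6 and 12.97 CPM and Cdh1 at 6.70 and 1.76 CPM, whereas Krt19, Krt7 and Epcam had 1 UMI or none in both.

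Biliary identity and acute phase genes had medians inside the range of random lists in hepatocyte-like cells, but their members went both ways. Of the biliary genes, Anxa2 (5.46), Sox4 (5.03), Cd24a (3.95), Spp1 (3.88) and Krt8 (1.74) were higher relative to the shift and Cdh1 (-1.79), Clu (-1.62) and Tm4sf4 (-1.50) lower, and Sox9 was at 0.028. Of the acute phase genes, Lcn2 (4.45), Orm2 (3.86), Saa2 (2.13) and Hp (1.55) were higher and Itih4 (-1.86), Hamp (-1.83), Fgl1 (-1.60) and Hpx (-1.42) lower. The YAP and TAZ target list held Birc5 (5.49), Klf6 (2.69), Ajuba (1.97) and Wwtr1 (1.21) on the higher and Cyr61 (-2.60) on the lower side.

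Log2 ratios went with the GC content of transcripts in hepatocyte-like cells, with a rank correlation of 0.330 across 8784 genes, which are not independent replicates. The correlation was 0.338 across 489 genes in T cell-like cells and 0.347 across 371 in B cell-like cells. It was 0.443 across the 349 genes whose level in T cell-like cells was above that of hepatocyte-like cells in both libraries, to which hepatocyte RNA adds little. These values are consistent with a GC content bias shared by the 3 classes, and a biological difference shared by them was not tested. Ribosomal protein genes were higher in lymphocyte-like cells of DKO, by medians of 0.13 in B cell-like and 0.12 in T cell-like cells relative to the shift. A GC correction gave 0.048 in T cell-like cells, but this test, written beforehand, was void because the median already lay under its bound of 0.3 before the correction, so the GC bias and other sources cannot be told apart for these genes.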
